A study of Arabidopsis thaliana with 12 samples.

How the data were processed

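Total RNA of wild-type Arabidopsis thaliana plants of the ecotype C24 was measured on 1-channel arrays. Per the labels, 6 samples came from plants grown in light specific for photosystem I (PSI light) and 6 from plants grown in that light and treated with DCMU, an inhibitor of photosynthetic electron transport. The dose, the length of treatment, the age of the plants, the tissue, the array's hybridisation protocol and the image analysis are not given in the sources used here.

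The deposited table held 1 linear intensity for each of 3439 probes in each of 12 columns. The values were relative: the brightest probe of each column stood at 100.0 and the lowest at 0. Whether the authors subtracted a background or applied another step before this scaling is not given in the sources used here. Column medians ran from 0.386 to 0.584, a spread of 51.2%, so the deposited intensity values were taken as not normalised between arrays. This spread lay largely between the groups: medians were 0.542 to 0.584 in PSI light and 0.386 to 0.504 with DCMU. Quantile normalisation removes such a difference, whatever its cause. The probe set at 100.0 also differed: probe 4141 in PSI light columns 1 to 4 and probe 1431 in the other columns. Totals ran from 3756 to 3903 in PSI light and from 3493 to 3652 with DCMU, and between 108 and 141 probes per column were listed at 0. Arrays have no read depth, and the number of arrays limits the precision.

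Intensities were quantile normalised between arrays, set to at least the 5th percentile of the positive values (0.110, or -3.19 on the log2 scale) and turned to log2. Fold changes of dim probes are understated by this floor. Of the 3439 probes, 167 stood at the floor in all 12 columns. The test was limma's moderated linear model (limma 3.58.1 in R 4.3.3) of PSI light + DCMU minus PSI light over the 12 columns, with Benjamini-Hochberg adjustment and a threshold of 0.05, as fixed before the data were examined. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

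The columns were compared before they were averaged. Within a group, the columns numbered 1 and 2, 3 and 4, and 5 and 6 had Spearman correlations of 0.976 to 0.991, against 0.921 to 0.960 for other pairs of that group. Their deviations from the group mean correlated at 0.464 to 0.728, and those of other pairs at -0.542 to -0.202. Such pairs were treated as duplicates of 1 hybridisation, which leaves 3 per group; the labels do not state this. Means and SDs are over the 3 duplicate means of a group, and the same limma model was run on these means. The labels do not say that samples came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

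Both models were tested on simulated data for the comparison of DCMU with PSI light. The 3439 simulated probes had the observed spread between hybridisations and between duplicates. Of them, 67 were changed by 0.5, 67 by 1 and 66 by 2 on the log2 scale, and the others were unchanged. Over 12 columns the model recovered 52.2%, 83.6% and 100.0% of probes changed by 0.5, 1 and 2 on the log2 scale, but 48.5% of its 305 calls fell on unchanged probes. On duplicate means it recovered 13.4%, 34.3% and 86.4%, and 8.25% of its 97 calls fell on unchanged probes. These shares depend on how many probes change. In the real data 2109 probes passed over 12 columns and 1483 over duplicate means. The simulated shares of false calls and of recovery therefore do not carry over to those calls. Given the false calls in the simulation, the p-values of the 12-column model are still taken as too small. Its counts are reported as the design stated, and the words rose and fell are used only for probes that also passed in the model of duplicate means, whose standard errors (SE) and adjusted p-values are the ones printed.

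Probes were named through the platform's annotation table, updated by gene identifier with the TAIR10.1 reference. It gave 1 gene for 692 probes, several for 870 and none for 1877, which are unnamed here. Of the 692, 2 had no gene in the reference and kept the platform's name. Probes with several genes were counted and not named. The files name no genome build, so no coordinates are given.

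Genes were named by a rule fixed before the data were examined. Among probes with 1 gene that passed in the 12-column model and whose 6 differences between same-numbered columns all had the fitted sign, it took the 12 with the largest positive and the 12 with the largest negative log2 fold change. From each of 21 gene lists fixed by locus, it took the 2 measured members with the smallest p. The lists held 362 genes of chloroplast, redox, starch, sugar, nitrogen, root and senescence functions. No reference name contradicted a listed one; for PRXIIE, FTRB, CHLP and the plastid ribosomal proteins the reference gives no such symbol, and the list's name was kept. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives.

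Other scalings, floors, filters on dim probes, variance models, a permutation test, the replicate number as a block and the loss of single columns were tried as alternatives listed beforehand. The loss of a whole hybridisation, a correction for position on the array and 2 further gene lists were added after seeing the data. The position correction subtracted the median deviation of neighbouring probes. Its layout was inferred from the order of the probe numbers, and no array coordinates were used. No sample was left out.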

Results

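The data were relative intensities of 3439 probes in 12 array columns of Arabidopsis thaliana, 6 from plants in light that mainly excites photosystem I and 6 from plants in the same light with DCMU. DCMU blocks electron transfer out of photosystem II. The comparison asks which transcripts differed when photosynthetic electron transport was inhibited in PSI light. Within each group the columns numbered 1 and 2, 3 and 4, and 5 and 6 correlated more closely than other columns did, and each such pair was counted as 1 replicate, so that n = 3 per group.

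**Figure D1:**
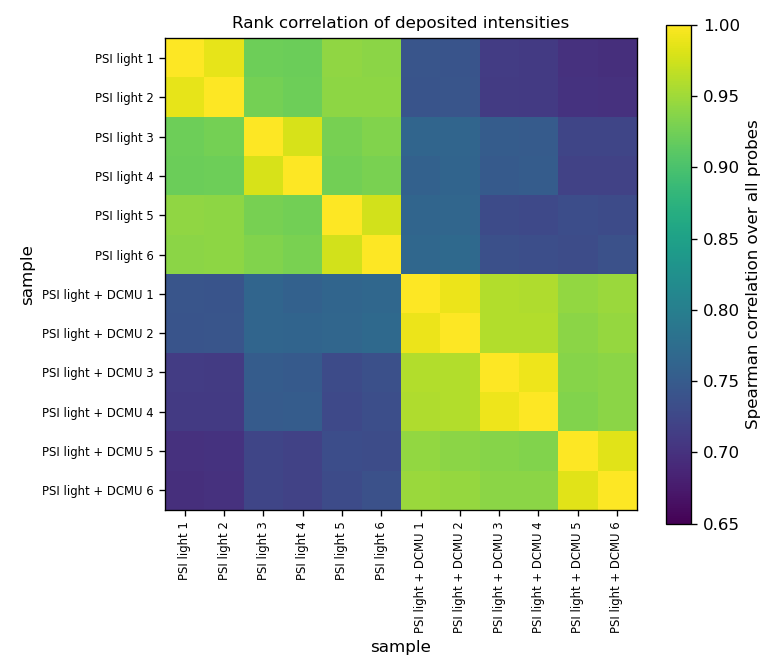
Spearman correlation over 3439 probes between each 2 of the 12 columns, with samples on both axes and the correlation as colour. Columns of different groups correlated at 0.697 to 0.770, columns of 1 group at 0.921 or above, and the pairs 1 and 2, 3 and 4, and 5 and 6 of a group at 0.976 or above.

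Transcript levels differed widely between PSI light with and without DCMU. The gene AT4G35660 rose 15.8-fold with DCMU, from -0.87 ± 0.95 to 3.11 ± 0.32 log2 relative intensity (SD, n = 3). Its PSI light level was 0.22 in the hybridisation of columns 3 and 4 and -1.50 and -1.32 in the others, and without that hybridisation the rise was 24-fold (log2 4.59). AT3G47980 fell 3.67-fold, from -0.98 ± 0.11 to -2.86 ± 0.27. The chloroplast genes PRK, for phosphoribulokinase of the Calvin cycle, and PRXIIE, for a plastid peroxiredoxin, rose 2.3-fold and 2.21-fold. NTRC, for a plastid thioredoxin reductase, and PRPL17, for a plastid ribosomal protein, fell 1.76-fold and 1.60-fold. Each of these 4 chloroplast genes lost its call in at least 1 of 13 other settings of the model of duplicate means. Measured genes for photosynthetic proteins did not share 1 direction after quantile normalisation. Most of them did not pass over duplicate means, and PSB27, for a photosystem II subunit, changed from -0.30 to 0.08 after a correction for position on the array.

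In limma's model of the 12 columns, 2109 of 3439 probes passed an adjusted p of 0.05, with 898 higher and 1211 lower with DCMU. In the same model of duplicate means, 1483 passed, with 624 higher and 859 lower, and 1478 probes passed in both. Among probes with 1 gene name, 422 of 692 passed over 12 columns (181 higher, 241 lower) and 302 over duplicate means (131 higher, 171 lower). Large changes after quantile normalisation were more often increases: of the probes past the threshold in duplicate means, 390 were higher and 274 lower by over 2-fold, and 74 were higher and 6 lower by over 4-fold. The first principal component held 72.4% of the variance and separated the 2 groups. The division into higher and lower depends on the scaling: 57.4% of the probes past the threshold over 12 columns were lower after quantile normalisation, 71.8% with no scaling, 67.7% with equal totals, 52.4% with cyclic loess and 48.2% with median centring. The share was 49.5% after a correction for position on the array. The median log2 fold change over all probes was -0.06 after quantile normalisation, -0.32 with no scaling, -0.23 with equal totals, 0.02 with cyclic loess and 0.03 with median centring; quantile, loess and median scaling bring it near 0 by construction. The fold changes given here are relative to the first of these.

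The 12 most raised genes with a single-gene probe had log2 fold changes of 2.25 to 3.98, with adjusted p-values of 0.00038 to 0.0137 over duplicate means. The naming rule required each to be higher in all 6 same-numbered pairs of columns. After AT4G35660 (3.98, SE 0.52), the gene AT2G30100 had the next largest rise at 3.04 (SE 0.26). AT3G56330, for a protein of the tRNA methyltransferase type, rose by 2.80 (SE 0.14), and AT4G14330, for a kinesin-type protein, by 2.69 (SE 0.07). The protein kinase gene AT5G40030 rose by 2.66 and the F-box protein gene AT2G23160 by 2.65. APTX, for an aprataxin-like protein, rose by 2.49 (SE 0.11), AT3G06870 by 2.44, and AT5G05400, for a protein of the disease resistance type, by 2.25. AT4G24930, for a thylakoid lumen protein, rose by 2.40 (SE 0.21). The probes of AT3G06870, AT4G14330, AT3G56330, AT4G24930 and AT2G30100 were numbered 3604, 3612, 3618, 3665 and 3678. Neighbours in this numbering tended to have similar fold changes, so these rises may not be independent of each other. After a correction for position on the array they stood at 2.28, 2.44, 2.57, 2.52 and 3.04, all past the threshold. AT5G46390, for a peptidase of the type that processes photosystem II proteins, and AT3G25680 stood at the floor in all 6 PSI light columns. Their rises of 5.72-fold and 5.26-fold therefore depend on the floor and the scaling, and were 5.1-fold and 4.68-fold with no scaling. The floor also set their spread in PSI light, so their p-values are uncertain. In PSI light, APTX and AT4G14330 were at the floor in 4 columns each, AT3G56330 and AT5G40030 in 3 each, and AT2G23160 in 2. The fold changes, SEs and p-values of these genes are thus set in part by the floor, including the small SEs of AT4G14330 and APTX. With an offset in place of the floor, AT3G56330 stood at 2.19, AT4G14330 at 2.11 and AT4G24930 at 1.77, and with the floor at the 10th percentile AT5G46390 stood at 1.92 and AT3G25680 at 1.80, all past the threshold.

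The 12 most lowered genes had log2 fold changes of -1.87 to -1.49, with adjusted p-values of 0.00057 to 0.0305 over duplicate means. Being lower in all 6 same-numbered pairs was again a condition of the naming rule. AT3G47980, for a membrane protein of the HPP family, fell by 1.87 (SE 0.16) and AT4G37420 by 1.79 (SE 0.38). AT1G03810 went from 2.52 ± 0.07 in PSI light to 0.80 ± 0.11 with DCMU (SD, n = 3). AT4G20760 fell by 1.68. Log2 fold changes were -1.63 for AT2G38500, for a protein of the oxygenase type, and -1.58 for AT4G22490, for a protein of the lipid transfer type. AT1G76450, for a protein with a PsbP domain, the domain of an extrinsic photosystem II subunit, fell by 1.60 (SE 0.19). GH9B8, for a glycosyl hydrolase of family 9, fell by 1.53 (SE 0.17). After a correction for position on the array, AT3G47980 stood at -1.29, AT4G22490 at -1.03 and GH9B8 at -0.82, all past the threshold. AT4G16060 stood at -1.07 and AT1G70350 at -1.08 after it, also past the threshold. Over duplicate means, AT2G38500 did not pass without any 1 of the 3 PSI light hybridisations or without columns 3 and 4 of the DCMU group (adjusted p = 0.0633 to 0.0878). AT4G37420 did not pass without PSI light columns 1 and 2 (adjusted p = 0.0598) or 3 and 4 (adjusted p = 0.0568), nor AT4G20760 without 1 and 2 (adjusted p = 0.0529) or 5 and 6 (adjusted p = 0.0507). The remaining genes were AT4G16060 at -1.56, AT5G59060 at -1.52, the F-box protein gene AT3G06570 at -1.49 and AT1G70350 at -1.49. With DCMU, AT4G16060 was at the floor in 3 columns, AT1G76450 in 2 and AT3G47980 in 1.

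**Figure D2:**
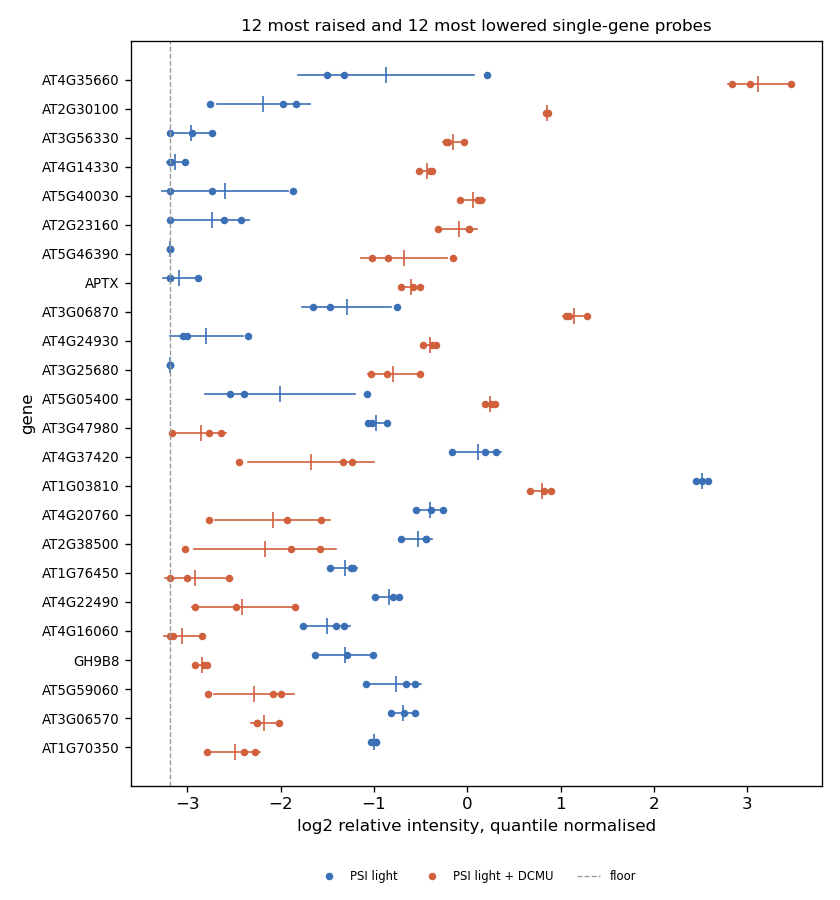
Log2 relative intensity (horizontal axis) of the 12 most raised and the 12 most lowered genes (vertical axis) in PSI light and in PSI light + DCMU. Points are the 3 duplicate means of a group, ticks their mean, lines the SD and the dashed line the floor at -3.19. Log2 fold changes ran from 2.25 to 3.98 for the raised and from -1.87 to -1.49 for the lowered genes.

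Of the 362 genes in the 21 fixed lists, 18 had a probe of their own, and these fell in 8 lists. Over duplicate means 2 of the 18 rose, 4 fell and 12 did not pass. Over 12 columns 5 were higher, 8 lower and 5 did not pass. Those that did not pass include PRPL29, which was at the floor in every column and could not pass. Of 13 other settings of the model of duplicate means, PRK and PRXIIE passed in 12 each, FTRB in 11, PRPL17 in 10, LHCB1.5 in 9 and NTRC in 6. PRK was lost without PSI light columns 1 and 2 (adjusted p = 0.0501) and PRXIIE with no scaling (adjusted p = 0.0521). NTRC was lost without any 1 hybridisation other than PSI light columns 3 and 4 (adjusted p = 0.0594 to 0.13), and PRPL17 without DCMU columns 1 and 2 (adjusted p = 0.0527) or 3 and 4 (adjusted p = 0.0561). PRPL17 was also lost after the position correction (log2 -0.22, adjusted p = 0.186). In the Calvin cycle list, PRK went from -1.20 ± 0.21 to 0.00 ± 0.38 (SD, n = 3; adjusted p = 0.014). SBPASE, for sedoheptulose-bisphosphatase, had a log2 fold change of 0.42 with an adjusted p of 0.0512 over all probes. Adjusted over the list alone, both Calvin cycle genes passed, at 0.0073 for PRK and 0.0224 for SBPASE, but SBPASE ranged from 0.07 with no scaling to 0.85 after the position correction. In the antioxidant list the single measured gene, PRXIIE, rose from -0.70 ± 0.37 to 0.44 ± 0.06 (adjusted p = 0.0106). That list held 31 genes, so PRXIIE does not show how antioxidant genes as a group changed. Both measured genes of the thioredoxin system fell, FTRB, for the catalytic subunit of ferredoxin-thioredoxin reductase, by 0.46 (adjusted p = 0.00819) and NTRC by 0.82 (adjusted p = 0.0481). Both also passed adjusted over the list alone, at 0.00307 and 0.0205. Over 12 columns, FTRB ranged from -0.85 with no scaling to -0.08 after the position correction, where it did not pass, and NTRC was -0.29 after that correction (adjusted p = 0.0283, or 0.148 over duplicate means).

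Among photosystem genes, LHCB1.5 (LHB1B2), for a chlorophyll-binding protein of the photosystem II antenna, fell by 0.58 (SE 0.09, adjusted p = 0.00881). This value is uncertain, since the gene is one of several near-identical Lhcb1 copies that can share a probe, and over 12 columns it did not pass with duplicates as a random block, with median centring (-0.04, adjusted p = 0.827) or after the position correction (-0.34, adjusted p = 0.052). None of the 3 measured photosystem II subunit genes passed over duplicate means: PSBY had a log2 fold change of 0.61 (adjusted p = 0.0561), PSB27 of -0.30 (0.114) and PSBW did not pass in either model. Over the alternatives PSBY ranged from 0.24 with no scaling to 1.37 after the position correction, and PSB27 from -0.40 to 0.08. PSAN, for a photosystem I subunit, had a log2 fold change of 0.24 (adjusted p = 0.323). Over 12 columns PSAN passed with median centring (0.48, adjusted p = 0.00884), with cyclic loess (0.38, adjusted p = 0.0149) and after the position correction (0.79, adjusted p = 7.78e-05). Of the chlorophyll synthesis genes, CHLM had a log2 fold change of -0.34 (adjusted p = 0.0801) and CHLP of 0.13 (adjusted p = 0.598). CHLM ranged from -0.71 with no scaling to 0.03 after the position correction, and CHLP from -0.06 with no scaling to 0.29 with median centring.

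Plastid ribosomal proteins were the only fixed list with at least 5 measured members. Of 6 measured, PRPL17 fell by 0.68 (SE 0.14, adjusted p = 0.0161) over duplicate means. The other 5 did not pass, with PRPL5 at 0.67 (adjusted p = 0.0506). PRPL29 was at the floor in all 12 columns and could not pass, but it enters the list's median and tests. PRPL17 ranged from -1.05 with no scaling to -0.22 after the position correction, and PRPL5 from 0.33 to 1.12 in the same settings. Over 12 columns 1 was higher and 3 lower; adjusted over the list alone, 4 passed over 12 columns and 1 over duplicate means. The list had a median log2 fold change of -0.38 and camera gave p = 0.537, or p = 0.630 with an estimated correlation. Lists for electron transport, carotenoids, starch, sugar starvation and darkness, plastid chaperones, light stress, protein import, nitrogen and sulfur, photorespiration, plastid RNA polymerases, oxylipins, non-green plastids and senescence had no member with a probe of its own.

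**Figure D3:**
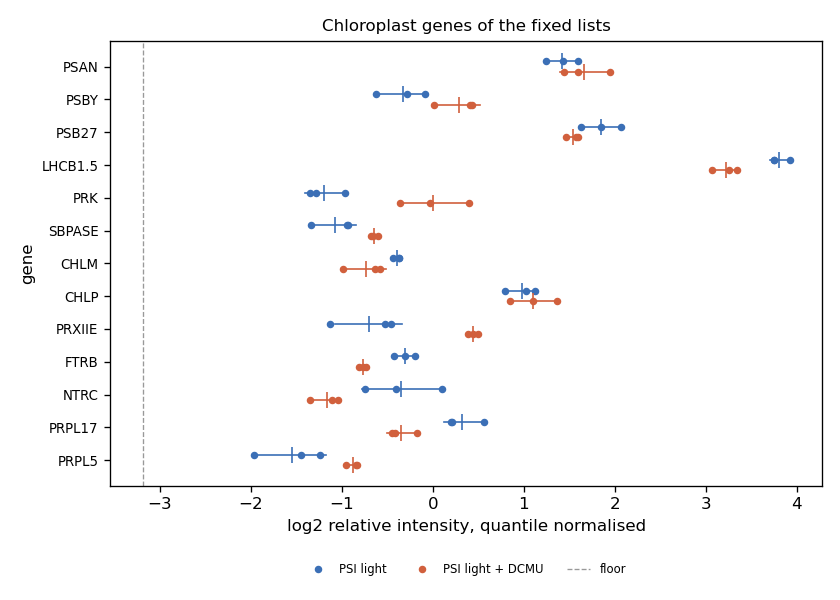
Log2 relative intensity (horizontal axis) of chloroplast genes taken from the fixed lists (vertical axis) in PSI light and in PSI light + DCMU, with the 3 duplicate means of a group as points, their mean as a tick and the SD as a line. PRK and PRXIIE were higher and LHCB1.5, FTRB, NTRC and PRPL17 lower with DCMU past the threshold.

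AT2G25870 was the single gene with 2 probes of its own, and they disagreed. One fell by 1.0 (SE 0.22, adjusted p = 0.0217) and the other had a log2 fold change of 1.04 (SE 0.13, adjusted p = 0.00445). This pair was singled out after its values were seen, and it limits how far the value of a single probe can be taken as that of the gene it is named for.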

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

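Of 80 groups of 6 columns examined for a column far from the others (37 named genes and the columns' medians, totals and zeros, each in both groups), 2 were picked out. About 4 would be expected by chance for independent columns, but the columns are treated here as duplicates, so that number does not hold. A hybridisation far from the others moves both of its columns and can be missed, as for AT4G35660 in PSI light (0.22 against -1.50 and -1.32). The few flags therefore do not show that the samples agree. AT4G14330 in PSI light stood at -2.85 in the column numbered 2, against -3.19 to -3.15 in the others (gap over range 0.887), and 4 of these columns were at the floor. FTRB in PSI light + DCMU stood at -0.92 in the column numbered 5, against -0.77 to -0.69 in the others (gap over range 0.670).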

How the results depend on the processing

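The alternatives were fixed before the data were examined, except the position correction, the loss of a whole hybridisation and the models of duplicate means under other settings, which were chosen after seeing the data. Counts of probes past the threshold stayed within 1.5 times their value except with the probes below the median brightness left out, where 1113 passed (481 higher, 632 lower), with fewer probes tested. Without 1 column 2034 to 2096 passed (858 to 892 higher, 1169 to 1205 lower), and without 1 hybridisation 1991 to 2096 (835 to 908 higher, 1136 to 1202 lower). Over duplicate means, 1394 to 1712 passed under the other settings (425 to 909 higher, 794 to 1172 lower), and after the position correction more were higher (909) than lower (803). There were 1151 to 1290 without 1 hybridisation (471 to 574 higher, 643 to 725 lower).

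With the replicate block, 2224 probes passed (964 higher, 1260 lower) over 12 columns and 1394 (580 higher, 814 lower) over duplicate means. Same-numbered columns of the 2 groups deviated together at 0.095 to 0.303, and number 2 was below 0.1, so the numbers were not taken to pair the samples. All 12 columns correlated best with their own number, a hint from the data and not from the design.

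The 24 most raised and lowered genes kept their sign in the alternatives tested. Apart from the averaging of duplicates, these alternatives were models of 12 columns. The naming rule took the largest fold changes with 1 sign in all 6 same-numbered pairs. A kept sign was therefore largely set in advance and is little evidence of robustness. In 13 settings of the model of duplicate means, chosen after seeing the data, all 24 kept their sign and 21 passed throughout; AT2G38500, AT4G20760 and AT4G37420 did not pass without some hybridisations. For 8 of the 24 the linear fold moved by over 1.5 times in at least 1 of these settings. PSB27 and CHLM changed sign with the position correction, to 0.083 and 0.034, and the cause was not tested. For plastid ribosomal proteins, p from limma's camera was 0.431 to 0.605 without 1 column and 0.362 to 0.702 without 1 hybridisation. The list's p from limma's fry, which does not compare it with other genes, was 0.011 over 12 columns and 0.121 over duplicate means. Gene lists were not run with duplicateCorrelation, the permutation test or the trended, robust variance model. Dim probes are limited by the floor, where 167 gave no fold change. Of the probes past the threshold over duplicate means, 33 stood at the floor in all 6 columns of 1 group, where the floor set their spread.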

Other observations

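Several gene groups outside the fixed lists were noticed after their values had been seen. The 4 glycosyl hydrolase family 9 genes with a probe of their own, enzymes of the cellulase type, all fell over duplicate means: GH9B8 at -1.53, GH9B16 at -1.21 (SE 0.18, adjusted p = 0.00753), GH9B12 at -0.89 (SE 0.16, adjusted p = 0.0111) and GH9B11 at -0.68 (SE 0.11, adjusted p = 0.00883). These decreases passed under each of the 4 other scalings; after the position correction GH9B11 stood at -0.16 (adjusted p = 0.343), and the other 3 passed, with GH9B8 at -0.82, GH9B12 at -0.47 and GH9B16 at -1.30. GH9B11 and GH9B12 are related genes that can share a probe's signal. Their probes, numbered 1490 and 1502, also counted as neighbours in the position correction. The decreases of these genes may therefore not be independent. Both measured genes for beta subunits of the plastid chaperonin rose, Cpn60beta3 by 0.84 (SE 0.10, adjusted p = 0.00423) and Cpn60beta4 by 1.12 (SE 0.16, adjusted p = 0.00608), the latter with 2 PSI light columns at the floor. Both also passed under the 4 other scalings and the position correction.

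Of 93 probes whose gene has a symbol other than its locus, 49 passed over duplicate means, 18 higher and 31 lower. The 4 largest changes each way among those not described elsewhere were named by a rule set after the values had been seen. On the lower side these were SIRB, for an enzyme of siroheme synthesis (-1.44, SE 0.07, adjusted p = 0.000666), SWAP70 (-1.37), AGL54 (-1.30) and UGT74D1, for a glycosyltransferase (-1.30). On the higher side these were ATATH8 (2.0, SE 0.30, adjusted p = 0.00731), SPL (1.53), GLX2-1, for a glyoxalase (1.51), and MAMI (1.43), with 3 PSI light columns at the floor for ATATH8 and 2 for GLX2-1. Of 13 other settings of the same model, SIRB, SWAP70, ATATH8 and SPL passed in all 13, AGL54 in 12, UGT74D1 in 11, MAMI in 9 and GLX2-1 in 7. After the position correction SIRB stood at -0.94, SWAP70 at -0.80, AGL54 at -0.75 and UGT74D1 at -0.43 (adjusted p = 0.0941). On the higher side, SPL stood at 0.92, MAMI at 1.25, ATATH8 at 1.95 and GLX2-1 at 2.06. The probes of SWAP70 (344) and SIRB (353) lay near that of AT4G16060 (355) in the numbering, so these decreases may not be independent. Without 1 hybridisation, AGL54 was lost once (adjusted p = 0.0508, PSI light columns 5 and 6), UGT74D1 once (0.05, PSI light columns 1 and 2), MAMI without PSI light columns 5 and 6 or DCMU columns 1 and 2 or 3 and 4 (0.0571 to 0.0647), and GLX2-1 in all but PSI light columns 1 and 2 (0.0752 to 0.108). With no scaling MAMI and GLX2-1 were lost too (0.0547 and 0.0507).

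Of the tests that follow, all except the counts over splits of the samples were chosen after the result was seen. In 100 splits drawn from the 462 of the 12 columns, 1 split, the real one, gave 2109 probes and the highest other gave 9. These splits part the duplicates of a hybridisation, which are not independent, so they do not exclude chance, although the test had been planned to do so. The 6 duplicate means allow 10 splits, too few for a share under 0.05; 1 split, the real one, gave 1483 and the highest other gave 0.

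After the values had been seen, the gene names prompted the hypothesis that genes of the NDH complex and of thylakoid assembly rise together under DCMU. All 10 genes listed for it had a probe of their own, against 18 of 362 in the fixed lists. Of the 10, CCB3 was at the floor in every column and could not pass. The p-values for this list come from the same data that prompted it and are not an independent test. Of 10 such genes, 2 rose and 1 fell over duplicate means: AT1G22700 (PYG7, photosystem I assembly) rose by 2.15 (SE 0.14, adjusted p = 0.00112), CRR41 by 1.71 (SE 0.21, adjusted p = 0.00431), and LPA19, for photosystem II assembly, fell by 0.94 (SE 0.11, adjusted p = 0.00339). ATAB2 also passed (adjusted p = 0.0472) but is not counted as a rise: it was at the floor in all 6 PSI light columns and 1 DCMU column, so that its spread in PSI light was set by the floor, and no fold is given. The list's median was 0.24, and camera with an estimated correlation on duplicate means gave p = 0.108, which leaves the hypothesis open. With the preset correlation camera gave p = 0.0485 on duplicate means and 0.0593 over 12 columns, or 0.146 and 0.178 adjusted over the lists tested. The unadjusted camera p over 12 columns was 0.034 to 0.0704 under the 4 other scalings and 0.269 after the position correction. The list's p from fry, which does not compare it with other genes, was 0.00209 on duplicate means and 3.6e-07 over 12 columns. The 9 measured photosynthesis and chlorophyll genes, pooled, gave camera p = 0.415 on duplicate means and p = 0.596 with an estimated correlation. Over 12 columns the pooled genes' p from limma's camera was 0.359, and 0.039 after the position correction, while fry's was 0.046, or 0.425 on duplicate means.

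Probes 6 positions apart in the numbering had similar fold changes, with a correlation of 0.30 across 2764 pairs of probes, which are not independent replicates. Uneven signal on single hybridisations would not recur between hybridisations, but the correlation between different ones had a mean of 0.244 and was 0.227 to 0.261 in the 6 combinations. Shared brightness of neighbours was not decided: fold change correlated with brightness at 0.009, and removing that trend moved nothing, leaving the correlation at 0.303. After the local median was subtracted, 78.5% of the 1483 kept their call and sign, and 1712 probes passed. This cannot decide how many calls position made, since the layout was inferred from the probe numbers. The root mean square log2 fold change went only from 0.828 to 0.776, but the calls shifted more. Of the 1483, 1164 kept their call and sign. Before the correction 624 probes were higher and 859 lower, and after it 909 were higher and 803 lower. A position effect that recurs in every array of a group, or an ordering of the probes by gene, may remain, and no biological explanation was tested.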
